A study of Homo sapiens with 24 samples.

How the data were processed

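Total RNA and gel-extracted small RNA under 35 nt from MDA-MB-231 cells were analysed, each as 8 libraries in 4 groups of 2. The groups were a control hairpin (shNC) or a hairpin against BCDIN3D (shBCDIN3D), each untreated or with 10 nM rapamycin for 24 h, and were taken from the sample titles. Total RNA was prepared with a stranded total RNA kit, per the labels' protocols. Ribosome profiling libraries are also described in the labels and were not analysed here, so translational efficiency was not computed.

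The deposited tables hold raw counts, in separate tables of total RNA reads per gene symbol, of small RNA reads per mature microRNA, and of small RNA reads per small RNA reference. There are 58648 names for total RNA and 2656 microRNAs. The small RNA references are 1880 microRNA precursors, 23439 piRNAs, 359 tRNAs, 4 rRNAs and 36 others. Per the submitters' processing notes, FastQC, cutadapt, TopHat2 2.0.8, HTSeq, STAR 2.5.2b, SAMtools and the build hg38 were used, with no role given for any of them. The strand setting, the annotation, the small RNA references and the treatment of multiply matching small RNA reads are not given in the sources used here. All 3 tables were used as deposited, and 0 sample columns were left unused.

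The closing entries of the total RNA table that name no gene were kept out of library sizes and tests. Reads on genes made up 35.7% to 47.5% of a library, reads that did not align uniquely 31.3% to 37.3%, reads on no feature 14.5% to 25.3% and ambiguous reads 1.7% to 3.4%. Since multiply aligned reads were set aside by the authors' counting, genes with near-identical copies, such as ribosomal protein genes with processed pseudogenes and clustered protocadherins, have uncertain counts. In the microRNA table, 39 of the 2252 microRNAs with at least 100 counts were identical to another microRNA in every library, so reads matching several sequences were counted for each. Names were matched to the GRCh38.p14 reference gene table by current or older symbol, which placed 34654 of 58648 names and 14806 of the 17459 tested. Mitochondrial genes and their nuclear copies were given no chromosome position.

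Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and all 8 libraries of a table were fitted together with 1 coefficient per group and no replicate term. Contrasts were tested with the quasi-likelihood F test and adjusted by Benjamini-Hochberg, with a threshold of 0.05. The fit compared shBCDIN3D with shNC in each treatment, rapamycin with untreated in each line, and tested the interaction. These comparisons, 24 gene lists, 8 microRNA lists, the alternatives and the rule for named genes were set before the data were examined. Contrasts averaged over the treatments or over the lines were added after the data had been seen. Lists were tested with camera at a preset correlation of 0.01 and at an estimated correlation, and with fry, in limma 3.58.1 on voom values, and were adjusted over the lists of a comparison.

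The named genes were BCDIN3D, ALDOC and the let-7 guides, the 8 genes with the largest rise and the 8 with the largest fall in each comparison, and the 2 to 4 called members of each list with the smallest p. The genes ranked by size had to pass the test, to average at least 5 CPM (counts brought to a common library size) over the libraries compared, and to have every library of a group above every library of the other. For a list with no called member, the 2 with the highest mean CPM were taken. Some genes that this rule picks are not reported here. Levels are TMM-scaled CPM with the SD over 2 libraries, and log2 fold changes are given with their standard error (SE).

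Neighbouring genes were examined on GRCh38.p14 with running medians of 31 genes of at least 5 CPM, against the 0.95 quantile of the largest median in 200 shuffles of gene order. Runs were taken from the shRNA change averaged over treatments. This step was added after the data had been seen.

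On simulated counts for the untreated shRNA comparison, in 16937 genes with 100 changed 2-fold and 100 changed 4-fold, the total RNA step called 94% and 100% of them, and 12 unchanged genes. The same test on 2349 microRNAs and on 8265 small RNA features called 0% of both sizes. All changed genes and features were drawn from those above the median level, so the 94% does not cover genes of lower level. The biological coefficient of variation was 0.14 for total RNA, 0.678 for microRNAs and 0.672 for the small RNA features. Total RNA libraries held 13791490 to 19612672 counts on genes, while microRNA libraries held 21167 to 1417097 counts. Intervals of shares are 95% Wilson intervals and cover counting error only.

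Alternatives were DESeq2 1.42.0, its size factors in edgeR, no low-count filter, at least 50 counts in every library, a replicate term, a fit of only the libraries compared, and leaving out each library in turn. Leaving out both shNC libraries with the most olfactory receptor reads, or the genes of the shifted runs, was added after the data had been seen. So was the microRNA fit without shBCDIN3D untreated replicate 1 and shNC rapamycin replicate 1. Replicate pairs differed by more than sampling noise in every group, with chi-square per degree of freedom of at least 11.6.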

Results

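The data came from MDA-MB-231, a human triple-negative breast cancer line, stably carrying a hairpin against BCDIN3D (shBCDIN3D) or a control hairpin (shNC). BCDIN3D is a methyltransferase that acts on the 5′ phosphate of histidine tRNA and of microRNA precursors. Each line was collected 48 h after seeding, untreated or after 24 h in 10 nM rapamycin, which inhibits the growth kinase complex mTORC1. The study's title names aldolase C, glycolysis and let-7, a family of microRNAs. Each of the 4 groups had 2 libraries of total RNA and 2 of small RNA, which the labels call biological replicates, and p-values measure the spread between these samples. Counts on genes in shNC replicates 1 and 2 were 13791490 and 19612672 untreated and 18354960 and 17968849 with rapamycin. In shBCDIN3D they were 17645558 and 17300253 untreated and 16214042 and 16091492 with rapamycin. Reads over 403 olfactory receptor genes, a family usually silent outside the nose, were most frequent in shNC untreated replicate 1 (23.4 CPM) and shNC rapamycin replicate 2 (11.5 CPM). The other 6 total RNA libraries had 1.39 to 4.91 CPM on these genes.

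The target of the hairpin was examined before other genes. BCDIN3D (chromosome 12, 49836043 to 49843106, GRCh38.p14) was at 2.49 ± 0.0101 CPM in untreated shNC cells and 0.961 ± 0.114 CPM in untreated shBCDIN3D cells (mean ± SD, n = 2), or 38.7% of the control. Its log2 fold change was -1.37 (SE 0.328, 95% interval -2.11 to -0.618), with an adjusted p of 0.0363 by edgeR quasi-likelihood and Benjamini-Hochberg. With rapamycin BCDIN3D was at 1.99 ± 0.326 CPM in shNC and 1.37 ± 0.405 CPM in shBCDIN3D, a log2 difference of -0.54 (SE 0.321, edgeR adjusted p = 0.328). The interaction was 0.83 (edgeR adjusted p = 1), so the reduction was not shown to differ between treatments. BCDIN3D rested on 16 to 47 counts per library, and DESeq2 gave the untreated change an adjusted p of 0.119. The untreated call ended without shNC untreated replicate 1 (edgeR adjusted p = 0.12), shNC untreated replicate 2 (0.103), shNC rapamycin replicate 1 (0.0509), shNC rapamycin replicate 2 (0.0521), shBCDIN3D untreated replicate 1 (0.186) and shBCDIN3D untreated replicate 2 (0.0868), with log2 changes of -1.49 to -1.24.

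ALDOC, which encodes the glycolytic enzyme aldolase C (chromosome 17, 28573120 to 28576895), was at 9.18 ± 2.91 CPM in untreated shNC and 3.88 ± 2.61 CPM in untreated shBCDIN3D cells (mean ± SD, n = 2). The log2 difference was -1.25 (SE 0.515, 95% interval -2.43 to -0.0805) and did not pass without a replicate term, with an edgeR adjusted p of 0.179. It was -0.68 without shBCDIN3D untreated replicate 1 (edgeR adjusted p = 0.519), -0.83 without shNC untreated replicate 2 (0.44) and -2.18 without shBCDIN3D untreated replicate 2 (0.0693). With rapamycin ALDOC was at 5.93 ± 2.7 CPM in shNC and 2.62 ± 1.32 CPM in shBCDIN3D, a log2 difference of -1.17 (SE 0.549, edgeR adjusted p = 0.216). Rapamycin itself went with a log2 difference of -0.64 (SE 0.498, edgeR adjusted p = 0.709) in shNC and -0.56 (SE 0.564, edgeR adjusted p = 0.693) in shBCDIN3D. ALDOC counts ran from 28 to 213 per library. Replicate 2 was above replicate 1 in every group (11.2 and 7.13, 7.84 and 4.02, 5.73 and 2.04, and 3.56 and 1.69 CPM). With a replicate term in the fit, the untreated ALDOC difference was -1.31 (SE 0.213) and passed (edgeR adjusted p = 0.00344). Whether untreated ALDOC passed thus depended on treating the replicate numbers as pairs. The labels tie no replicate number to a shared batch or day, so the data do not settle which fit applies. Averaged over the treatments, a contrast added after the data had been seen, ALDOC fell to 43.2% of the control (log2 -1.21, SE 0.376, edgeR adjusted p = 0.0472) and BCDIN3D to 51.7% (-0.95, SE 0.23, edgeR adjusted p = 0.0184). The averaged ALDOC call ended without shNC untreated replicate 1 (edgeR adjusted p = 0.0553), shNC untreated replicate 2 (0.108), shNC rapamycin replicate 2 (0.158), shBCDIN3D untreated replicate 1 (0.107), shBCDIN3D rapamycin replicate 1 (0.147) and shBCDIN3D rapamycin replicate 2 (0.0533). The averaged BCDIN3D call ended without shNC rapamycin replicate 2 (0.0668), shBCDIN3D untreated replicate 1 (0.0585) and shBCDIN3D rapamycin replicate 1 (0.0619), and in DESeq2 (0.0688).

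**Figure D1:**
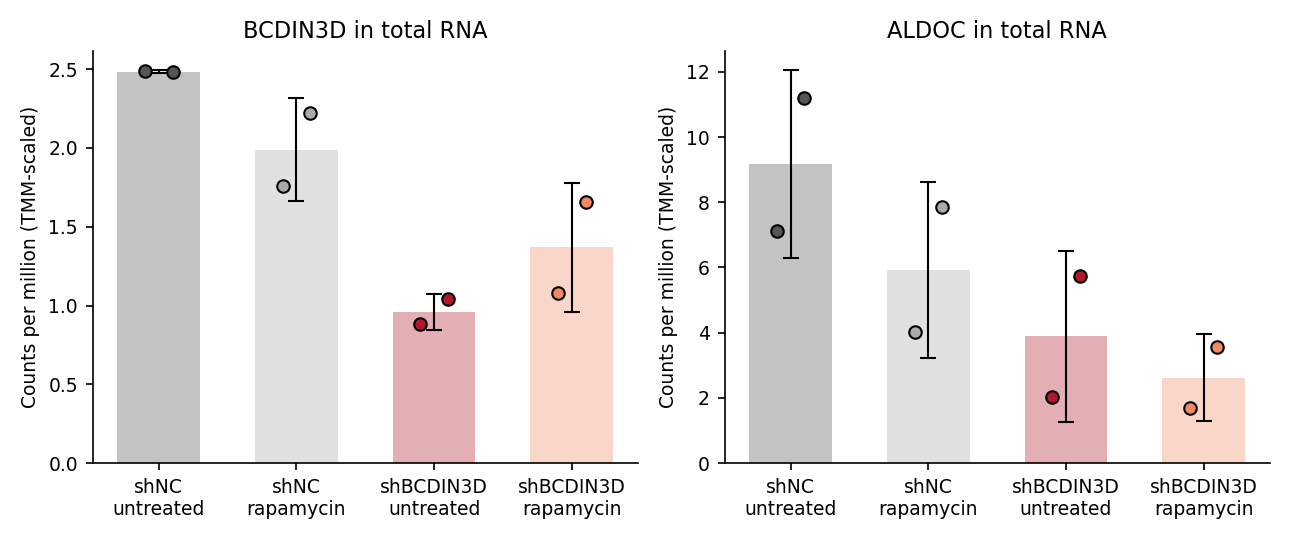
TMM-scaled CPM of BCDIN3D and ALDOC in the 4 groups of total RNA libraries, with bars for the mean, whiskers for the SD and a point for each of the 2 libraries per group. Untreated BCDIN3D falls from 2.49 to 0.961 CPM, and the untreated ALDOC libraries lie at 7.13 and 11.2 CPM in shNC and at 2.04 and 5.73 CPM in shBCDIN3D.

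The untreated lines were compared to find which transcripts differed with the BCDIN3D hairpin. Among the largest rises, NGFR, the low-affinity neurotrophin receptor, went from 29.2 ± 4.82 to 449 ± 13.6 CPM (log2 3.94, SE 0.128, edgeR adjusted p = 7.28e-06). FAM133A rose from 0.868 ± 0.183 to 25.9 ± 1.68 CPM (log2 4.91, SE 0.191), and RNF144A, a ubiquitin ligase, went from 0.24 ± 0.265 to 16 ± 4.32 CPM. NHSL2 (log2 3.49, SE 0.246), the metalloprotease ADAM12 (2.80, SE 0.409), the thrombin receptor F2RL3 (2.59, SE 0.335), the sodium channel SCN9A (2.07, SE 0.283) and the clustered protocadherin PCDHB9 (2.07, SE 0.305) also rose. Among the largest falls, the chemokine receptor CXCR4 went from 19.2 ± 2.20 to 0.116 ± 0.164 CPM, cadherin-11 (CDH11) from 66.5 ± 8.61 to 0.634 ± 0.741 CPM, and the calcium channel subunit CACNA2D4 from 10.3 ± 0.319 to 0.172 ± 0.166 CPM. PAPPA, a protease of insulin-like growth factor binding proteins (log2 -5.80, SE 0.394), the guidance cue SEMA5A (-4.82, SE 0.664), the atypical cadherin FAT3 (-4.72, SE 0.316) and the adhesion protein MPZL2 (-4.69, SE 0.514) fell as well. ELF3, an epithelial transcription factor, went from 9.87 ± 8.81 to 0.313 ± 0.131 CPM (edgeR adjusted p = 0.0416). RNF144A in shNC and the genes that fell rested on few counts per library on their low side, so their levels say more than their folds. All levels are means ± SD with n = 2.

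In total 1531 of 17459 tested genes passed in the untreated comparison by edgeR quasi-likelihood with Benjamini-Hochberg, 701 higher and 830 lower in shBCDIN3D, and 590 of them changed over 2-fold. DESeq2 called 1665. Leaving out shNC untreated replicate 1, shNC untreated replicate 2 or shBCDIN3D untreated replicate 1 lowered the count to 686, 912 and 594, and leaving out both shNC libraries with the most olfactory receptor reads lowered it to 696. Of the 16 genes named by size, ELF3 alone lost its call in this way, without shNC untreated replicate 2 (edgeR adjusted p = 0.121), shBCDIN3D untreated replicate 1 (0.224), shBCDIN3D untreated replicate 2 (0.136), shBCDIN3D rapamycin replicate 1 (0.0652) and shBCDIN3D rapamycin replicate 2 (0.0632).

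Gene groups were then compared in the untreated lines. Of 26 genes of glycolysis, 1 rose and 6 fell over all genes tested, and 3 rose and 9 fell when adjusted over the list alone. The falls included GAPDH (log2 -0.52, SE 0.086), the phosphofructokinase regulator PFKFB2 (-1.17, SE 0.21) and lactate dehydrogenase A (LDHA, -0.44, SE 0.0798), and the rise was pyruvate kinase (PKM, 0.74, SE 0.0798). The list median was -0.233. By camera the adjusted p was 0.0439 (adjusted p = 0.825 with an estimated correlation). Of 78 ribosomal protein genes, 1 rose and 7 fell, and 1 and 12 when adjusted over the list alone. RPL11 (-0.81, SE 0.0945), RPL8 (-0.70, SE 0.1), RPL22 (-0.66, SE 0.103) and RPL28 (-0.41, SE 0.0839) were among the falls. Of the 78 values 72 were negative (median -0.21, camera adjusted p = 6.91e-09, and adjusted p = 0.825 with an estimated correlation). All 17 inflammatory NF-kB genes had negative values (median -1.23, camera adjusted p = 0.000509, and adjusted p = 0.825 with an estimated correlation). Of them 3 fell, or 5 when adjusted over the list alone. The 3 were the neutrophil chemokine CXCL1 (-1.86, SE 0.456), the cytokine IL1B (-3.91, SE 0.998) and TNFAIP2 (-0.80, SE 0.209). Of 13 epithelial genes, 7 fell by both adjustments (median -0.761, camera adjusted p = 0.000517, and adjusted p = 0.825 with an estimated correlation), among them the splicing regulator ESRP2 (-3.09, SE 0.306) and the keratins KRT7 (-0.76, SE 0.129), KRT18 (-0.98, SE 0.167) and KRT8 (-0.97, SE 0.173). Of 26 sterol and lipid synthesis genes 0 passed singly (also 0 when adjusted over the list alone), with SCD, a fatty acid desaturase, at -0.36 (SE 0.513) and 25 of 26 values negative (camera adjusted p = 0.0026, and adjusted p = 0.825 with an estimated correlation). Of 30 ribosome biogenesis genes the polymerase I subunit POLR1A rose (0.58, SE 0.107) and nucleolin (NCL) fell (-0.46, SE 0.1), with 1 and 2 when adjusted over the list alone (camera adjusted p = 0.0132, and adjusted p = 0.825 with an estimated correlation). By fry none of these lists passed, with adjusted p from 0.107 to 0.51.

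Other groups held changed members without passing as lists. Of 48 let-7 target genes the chromatin protein HMGA1 rose (log2 0.84, SE 0.108), and the repair protein ERCC6 (-0.66, SE 0.132) was among 2 that fell, the same 1 and 2 as adjusted over the list alone (camera adjusted p = 0.501). In the mesenchymal list of 22, collagen COL1A2 (-3.35, SE 0.316) and collagenase MMP1 (-3.49, SE 0.343) fell, and ZEB1 (0.66, SE 0.115) and MMP14 (0.56, SE 0.115) rose, with 2 and 3 when adjusted over the list alone (camera adjusted p = 0.767). Among 16 p53 targets 4 rose and 2 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.357), including TP53I3 (1.18, SE 0.117), TP53INP1 (0.97, SE 0.128), BTG2 (-3.58, SE 0.717) and the cell cycle inhibitor CDKN1A (-1.88, SE 0.413). Of 16 YAP and SRF targets, tissue factor (F3, -0.95, SE 0.0983), smooth muscle actin (ACTA2, -1.79, SE 0.253) and CRIM1 (-0.47, SE 0.0744) fell and transgelin (TAGLN, 1.61, SE 0.304) rose, as when adjusted over the list alone (camera adjusted p = 0.401). Of 32 lysosome and autophagy genes 4 rose, among them the kinase ULK1 (0.84, SE 0.114), and the GTPase RRAGD fell (-1, SE 0.168), as when adjusted over the list alone (camera adjusted p = 0.0981). Hypoxia genes (camera adjusted p = 0.28) had NDRG1 (-0.99, SE 0.202) and VEGFA (-0.75, SE 0.168) lower and the demethylase KDM3A higher (0.49, SE 0.107), and 3 each way when adjusted over the list alone. Interferon genes (camera adjusted p = 0.333) had 2 calls each way, with the antiviral synthetase OAS3 lower (-0.73, SE 0.111) and the RNA sensor DDX58 higher (0.66, SE 0.139), with 2 and 3 when adjusted over the list alone. Of the amino acid synthesis and ATF4 list (camera adjusted p = 0.168) the proline enzyme PYCR1 (-0.59, SE 0.116) and the serine enzyme PHGDH (-2.23, SE 0.487) fell, 3 when adjusted over the list alone.

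The remaining lists of the untreated comparison also did not pass by camera, and their counts adjusted over the list alone equalled the counts over all genes except where given. The proliferation list had MKI67 higher (log2 1.26, SE 0.263, camera adjusted p = 0.28), and the microRNA biogenesis list TNRC6B, a partner of Argonaute (0.56, SE 0.105, camera adjusted p = 0.277). Translation genes with a 5′ terminal oligopyrimidine (TOP) tract other than ribosomal proteins had the poly(A)-binding protein PABPC1 (0.72, SE 0.133) and EIF3H (0.43, SE 0.082) higher and EEF1B2 lower (-0.38, SE 0.0943), with 2 and 5 when adjusted over the list alone (camera adjusted p = 0.138). Mitochondrial ribosome genes had MRPS15 (-0.68, SE 0.102) and MRPL20 (-0.57, SE 0.0936) lower (camera adjusted p = 0.141). Nuclear oxidative phosphorylation genes had CYC1 (-0.54, SE 0.11) and SDHB (-0.44, SE 0.0908) lower and COX6C higher (0.55, SE 0.126, camera adjusted p = 0.646). The partners of histidine tRNA did not pass as a list (camera adjusted p = 0.277). Neither mitochondrially encoded genes, at MT-CO1 -0.05 (SE 0.12) and MT-CO3 0.12 (SE 0.114), nor replication histones, at HIST1H1E 0.05 (SE 0.127) and HIST1H2AG 0.14 (SE 0.192), had a called member by edgeR or, in these 2 lists, when adjusted over the list alone (camera adjusted p = 0.646 and 0.165). Markers of other cell types went both ways. Of 3 haematopoietic markers the actin bundler LCP1 fell (-2.97, SE 0.433, camera adjusted p = 0.277), and of 7 fibroblast and endothelial markers collagen COL6A3 (2.00, SE 0.183) and the VEGF receptor KDR (1.10, SE 0.166) rose (camera adjusted p = 0.33). Of the 75 called genes picked for this comparison by the naming rule, 33 kept their call whichever library was left out. Calls were lost by 26 genes without shNC untreated replicate 1, 31 without shNC untreated replicate 2, 35 without shBCDIN3D untreated replicate 1 and 18 without shBCDIN3D untreated replicate 2, and by 6, 6, 8 and 8 without the rapamycin libraries of shNC and of shBCDIN3D. The highest edgeR adjusted p so reached was 0.276, for TNFAIP2.

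**Figure D2:**
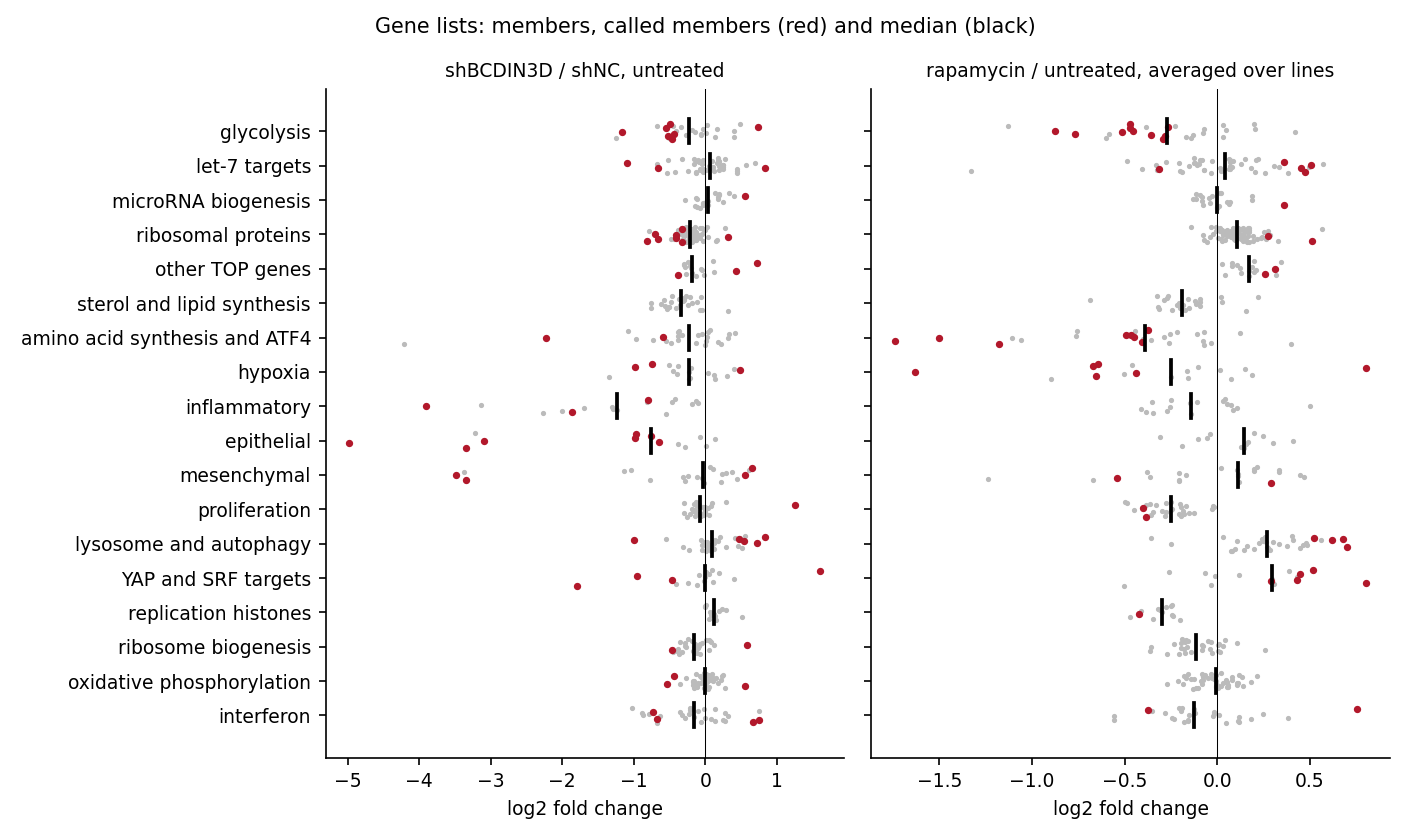
Log2 fold changes of the members of 18 gene lists, untreated shBCDIN3D over shNC on the left and rapamycin over untreated averaged over the lines on the right, with called members in red and the list median as a black bar. The inflammatory median lies at -1.23 on the left, and the amino acid synthesis and ATF4 median at -0.388 on the right.

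With rapamycin present, the comparison of the lines asked whether the same transcripts differed in treated cells. NGFR went from 26.3 ± 0.558 to 420 ± 25 CPM (mean ± SD, n = 2, log2 4, SE 0.128, edgeR adjusted p = 6.62e-06), FAM133A rose (5.95, SE 0.212) and RNF144A went from 0.0551 ± 0.0779 to 15 ± 2.04 CPM. The unconventional myosin MYO7B (3.63, SE 0.542), ADAM12 (3.23, SE 0.438), F2RL3 (2.66, SE 0.344), the phosphatase PTPN22 (2.43, SE 0.22) and KNDC1 (2.33, SE 0.29) also rose. CDH11 went from 55.3 ± 9.42 to 0.491 ± 0.694 CPM, CXCR4 from 18.2 ± 2.14 to 0.215 ± 0.304 CPM and CACNA2D4 from 16 ± 2.45 to 0.215 ± 0.304 CPM. SEMA5A (-5.19, SE 0.633), PAPPA (-5.16, SE 0.363), the ribosomal S6 kinase RPS6KA2 (-4.77, SE 0.454) and the teneurin TENM3 (-4.54, SE 0.641) fell, as did ELF3 from 12.1 ± 12.8 to 0.397 ± 0.306 CPM (edgeR adjusted p = 0.0342).

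In the rapamycin libraries 23 of 78 ribosomal protein genes were lower in shBCDIN3D and 0 higher (49 and 1 when adjusted over the list alone, camera adjusted p = 3.53e-15, adjusted p = 0.683 with an estimated correlation, fry adjusted p = 0.0219), with RPL11 at -0.84 (SE 0.0946), RPL8 at -0.84 (SE 0.101) and RPL28 at -0.43 (SE 0.0839). Other TOP genes had 2 higher and 4 lower, among them the elongation factor EEF2 (-0.37, SE 0.0723), and 2 and 8 when adjusted over the list alone (camera adjusted p = 0.0106, adjusted p = 0.683 with an estimated correlation, fry adjusted p = 0.0219). Of the glycolysis list 1 rose and 8 fell (2 and 9 adjusted over the list alone), including aldolase A (ALDOA, -0.59, SE 0.0939), GAPDH (-0.58, SE 0.0861) and the triose phosphate isomerase TPI1 (-0.54, SE 0.0983), and PKM rose (0.83, SE 0.0799, camera adjusted p = 0.0348, adjusted p = 0.806 with an estimated correlation). Proliferation genes had TOP2A (-0.51, SE 0.0952), CDK1 (-0.43, SE 0.104) and MCM7 (-0.49, SE 0.122) lower and MKI67 higher (1.01, SE 0.262), with 1 and 6 when adjusted over the list alone (camera adjusted p = 1.15e-05, adjusted p = 0.806 with an estimated correlation). In the amino acid synthesis and ATF4 list 5 of 26 fell by both adjustments, including the glutamine transporter SLC1A5 (-0.77, SE 0.139) and the folate enzyme MTHFD2 (-0.64, SE 0.118, camera adjusted p = 0.00618, adjusted p = 0.806 with an estimated correlation). The epithelial list again had 7 of 13 lower by both adjustments (camera adjusted p = 0.000627, adjusted p = 0.683 with an estimated correlation), with E-cadherin (CDH1) at -4.21 (SE 0.664). The inflammatory list had 2 lower, CXCL1 (-1.76, SE 0.477) and IL1B (-3.68, SE 0.931), and 5 when adjusted over the list alone (camera adjusted p = 0.000778, adjusted p = 0.806 with an estimated correlation).

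By edgeR quasi-likelihood with Benjamini-Hochberg 1909 genes passed with rapamycin, 893 higher and 1016 lower in shBCDIN3D, and DESeq2 called 1928. The untreated and rapamycin comparisons share no library, but they compare the same 2 lines in 1 fit of all 8 libraries. They had 1256 calls in common, all in the same direction. Independent lists of these sizes would share 84.2 in the same direction. Any lasting difference between the lines would raise the overlap above that, whatever its cause. Across genes, which are not independent replicates, the log2 changes of the 2 comparisons correlated with Pearson r = 0.825 and Spearman rho = 0.753. Of the 1531 genes called untreated, 1530 had the same sign with rapamycin. The count of 1909 became 816, 658, 751 and 653 without shNC rapamycin replicate 1, shNC rapamycin replicate 2, shBCDIN3D rapamycin replicate 1 and shBCDIN3D rapamycin replicate 2, and 580 without the pair of shNC libraries rich in olfactory receptor reads. Of 84 called genes picked by the naming rule for this comparison, 49 lost their call without some library, 32 of them without shNC rapamycin replicate 1, 41 without shNC rapamycin replicate 2, 33 without shBCDIN3D rapamycin replicate 1 and 41 without shBCDIN3D rapamycin replicate 2. These included ELF3, whose highest edgeR adjusted p was 0.189. Without an untreated library, at most 4 of the 84 calls ended.

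**Figure D3:**
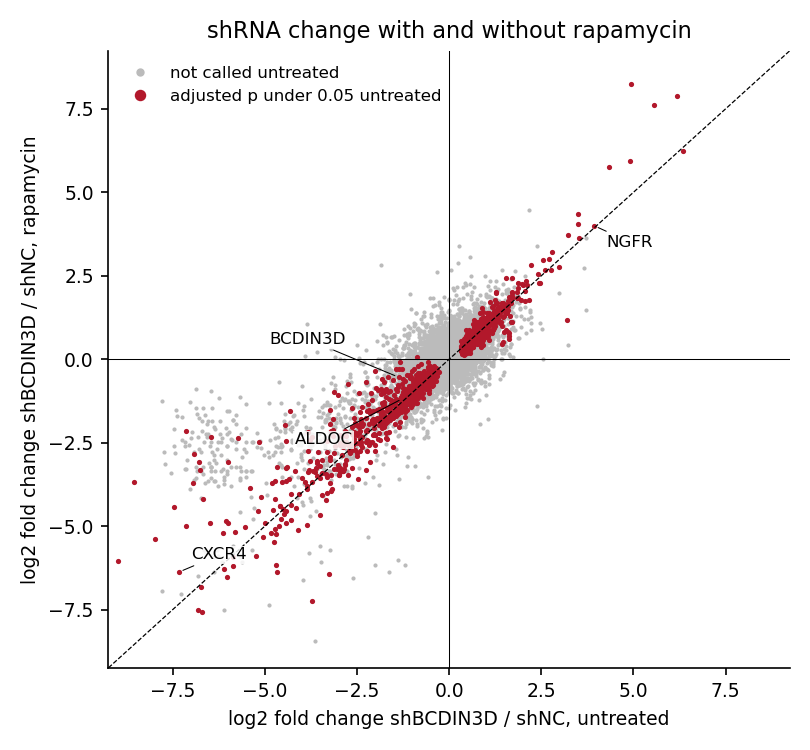
Log2 fold change of shBCDIN3D over shNC for every tested gene, untreated on the x axis and with rapamycin on the y axis, with a point per gene, genes called untreated in red and the line of equal change dashed. Across the 1531 red points r is 0.953, and NGFR lies near the line at 3.94 and 4.

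Some differences between the lines fell on neighbouring genes. On chromosome 10, from 124984317 to 133422520 (GRCh38.p14), all 23 placed genes were higher in untreated shBCDIN3D cells, with a median log2 change of 1.00 (SD 0.488 over genes) and 22 called. That stretch holds ADAM12, KNDC1 and MKI67. On chromosome 15 the stretch from 70829130 to 74630201, which holds PKM, had a median of 0.99 over 18 genes, and the stretch from 77420888 to 101724473 a median of -0.51 over 81 genes. On chromosome 2, from 218136 to 26290465 and including RNF144A, 63 of 65 genes were higher (median 0.62). On chromosome 1, from 16246840 to 33166795, 156 of 166 genes were lower (median -0.42). On chromosome 8 the medians were 0.50 from 78666089 to 103415107 and -0.37 from 142727223 to 145056030, which holds RPL8. There were 15 such runs of 218 Mb together, with the others on chromosomes 1, 2, 3 and 10 and medians from -0.39 to 0.56. They held 402 of the 1531 genes called untreated (26.3%), 6.82% of the genes tested and 87 of the 590 that changed over 2-fold. Without their genes the untreated comparison called 980. TP53I3, TP53INP1, ZEB1, KDM3A, PABPC1, BNIP3, IFI6, RPL11, RPL22, MRPS15, MRPL20, CYC1, SDHB and COX6C also lie in them. Outside the runs, the list results for untreated glycolysis (22 genes, camera adjusted p = 0.00253, adjusted p = 0.798 with an estimated correlation) and ribosomal proteins (69 genes, camera adjusted p = 3.56e-11, adjusted p = 0.619 with an estimated correlation) kept their direction. In the rapamycin libraries the median of each run lay within 0.1 of its untreated value, at 1.08 for the end of chromosome 10. Since the runs were picked from the average of both comparisons, the shared directions within them and this closeness were favoured in advance. Rapamycin itself, averaged over the lines, moved none of these runs by a median of more than 0.106 in size. Rapamycin had windows past its own threshold, 39 in shBCDIN3D (up to 0.38 in size), 0 in shNC and 30 averaged over the lines (up to 0.205), out of 10237.

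**Figure D4:**
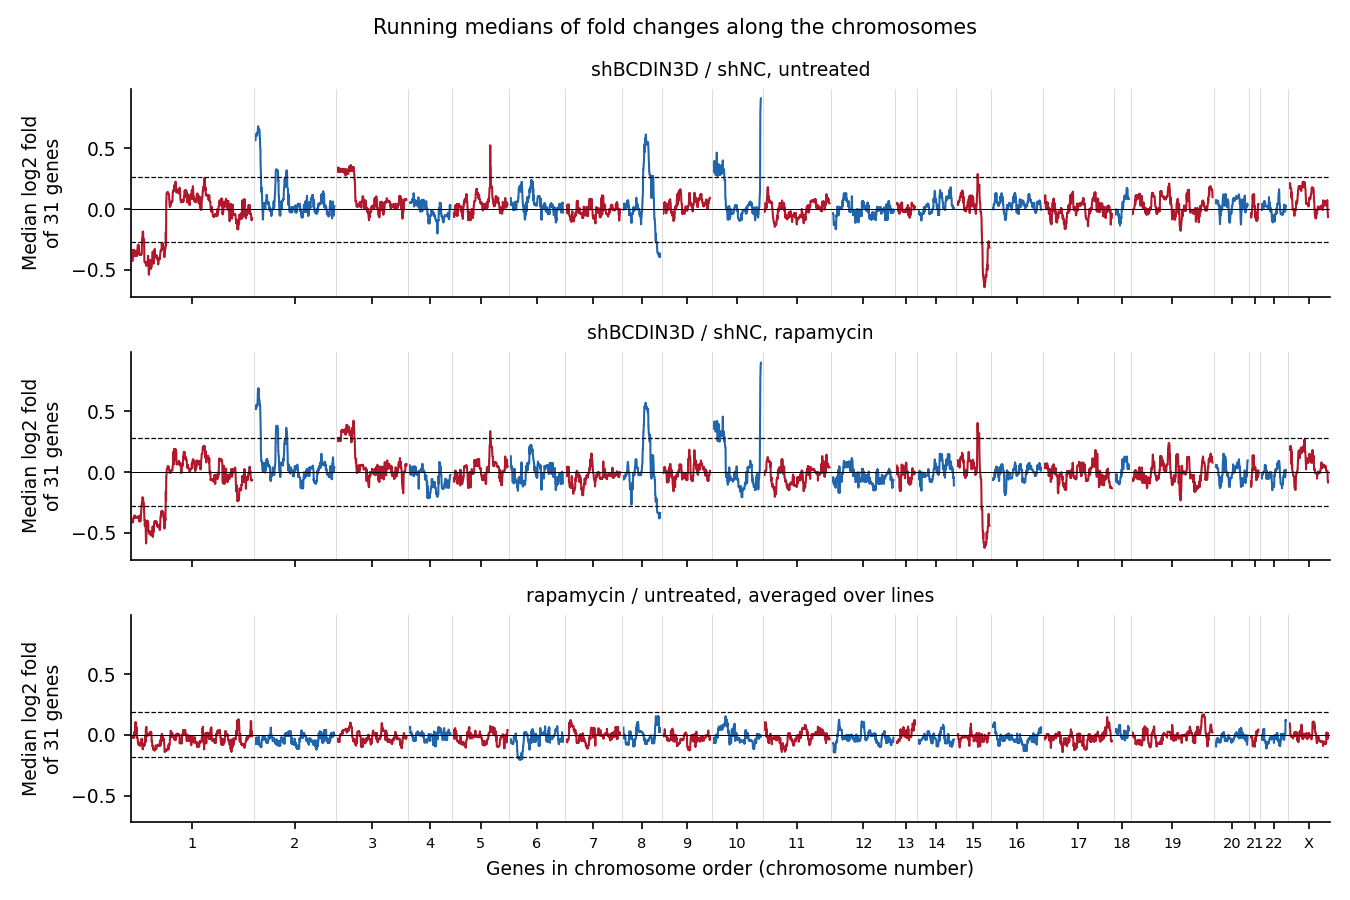
Running median log2 fold change of 31 neighbouring genes along the chromosomes, for shBCDIN3D over shNC untreated (top) and with rapamycin (middle) and for rapamycin over untreated averaged over the lines (bottom), with dashed lines at the 0.95 quantile of 200 shuffles of gene order. The largest medians are 0.912 untreated and 0.899 with rapamycin, both at the end of chromosome 10, against 0.205 for rapamycin over untreated.

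Rapamycin was compared with no treatment in each line. In shNC cells, PDCD4, an inhibitor of translation initiation that is degraded after mTORC1 signalling, rose from 51.4 ± 1.87 to 102 ± 6.2 CPM (n = 2, log2 0.99, SE 0.122, edgeR adjusted p = 0.0475). MTURN (0.83, SE 0.0934), the sialic acid lectin CD22 (0.77, SE 0.0872) and TBC1D8 (0.76, SE 0.0899) rose. MYH15, a myosin heavy chain (-1.84, SE 0.128, edgeR adjusted p = 0.00463), the matrix protein tenascin C (TNC, -1.43, SE 0.153), the kinase PAK6 (-1.09, SE 0.132), AGFG2 (-0.83, SE 0.0985) and LDHA (-0.81, SE 0.0802) fell, the last from 1745 ± 15.9 to 995 ± 24.2 CPM. In shBCDIN3D cells PSG4 (1.42, SE 0.161), MTURN (0.91, SE 0.0916), TBC1D8 (0.87, SE 0.0923) and CD22 (0.87, SE 0.0875) rose. The serine synthesis enzyme PSAT1 (-1.77, SE 0.178), MYH15 (-1.59, SE 0.12), asparagine synthetase (ASNS, -1.35, SE 0.141) and LDHA (-0.72, SE 0.0802, edgeR adjusted p = 0.0288) fell.

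These 9 genes in shNC and 8 in shBCDIN3D were all that passed by edgeR with Benjamini-Hochberg, without a replicate term and with the low-count filter. Of them 5 were shared with the same sign (MTURN, CD22, TBC1D8, MYH15 and LDHA). DESeq2 called 198 and 283, edgeR with a replicate term 301 and 602, and edgeR with no low-count filter 393 and 620. All 17 calls ended when some library was left out. The shNC count was 0 without shNC untreated replicate 1, shNC rapamycin replicate 1 or shNC rapamycin replicate 2, where 1830 genes had an unadjusted p under 0.05 with all libraries. It was 1 without shNC untreated replicate 2, 2 without either shBCDIN3D rapamycin replicate, and 31 without both shNC libraries rich in olfactory receptor reads. The shBCDIN3D count was 0 without shBCDIN3D untreated replicate 1 or either shBCDIN3D rapamycin replicate, 1 without shBCDIN3D untreated replicate 2 or either shNC rapamycin replicate, 2 without shNC untreated replicate 1, and 0 without both shNC libraries rich in olfactory receptor reads. With all libraries 2505 genes had an unadjusted p under 0.05 in shBCDIN3D.

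Averaged over both lines, a contrast added after the data had been seen, rapamycin changed 686 genes by edgeR, 375 higher and 311 lower, and 52 over 2-fold, while DESeq2 called 1091. The BMP regulator KCP (log2 2.49, SE 0.304), PSG4 (1.32, SE 0.111), KLHL24 (1.25, SE 0.162), MEGF6 (1.13, SE 0.253), the transcriptional regulator CREBRF (1.01, SE 0.116), ABTB1 (1.01, SE 0.0982), PDCD4 (0.95, SE 0.086) and the WNT antagonist DKK1 (0.94, SE 0.093) rose. MYH15 (-1.72, SE 0.0879), PSAT1 (-1.50, SE 0.125), PPFIA4 (-1.44, SE 0.188), the lipid transporter MFSD2A (-1.30, SE 0.152), ASNS (-1.18, SE 0.099), arginase 2 (ARG2, -1.10, SE 0.115), PFKFB4 (-0.88, SE 0.13) and CSPG5 (-0.87, SE 0.132) fell. Leaving out shNC untreated replicate 1, shNC untreated replicate 2, shNC rapamycin replicate 1, shNC rapamycin replicate 2, shBCDIN3D untreated replicate 1, shBCDIN3D untreated replicate 2, shBCDIN3D rapamycin replicate 1 and shBCDIN3D rapamycin replicate 2 in turn gave 188, 302, 103, 76, 232, 399, 183 and 74 calls, and leaving out both shNC libraries rich in olfactory receptor reads gave 66. Of the 50 called genes picked by the naming rule, list members included, these steps ended 23, 17, 31, 29, 21, 13, 25 and 28 calls in that order. Of the 16 genes named by size, MEGF6 (edgeR adjusted p up to 0.183), PFKFB4 (0.0543) and CSPG5 (0.0755) were among them.

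By gene group, 10 of 26 glycolysis genes fell and 0 rose on average (12 and 2 when adjusted over the list alone), including LDHA (log2 -0.77, SE 0.0567), the kinase PDK1 (-0.52, SE 0.0644) and TPI1 (-0.47, SE 0.0694, camera adjusted p = 3.57e-07, adjusted p = 0.543 with an estimated correlation, fry adjusted p = 0.0909). Camera passed this list in each line, with adjusted p = 4.63e-07 in shNC and 9.83e-07 in shBCDIN3D (adjusted p = 0.439 and 0.544 with an estimated correlation). Of the amino acid synthesis and ATF4 list 8 of 26 fell (14 when adjusted over the list alone), including PSAT1, ASNS, the stress enzyme CHAC1 (-1.74, SE 0.204) and the mitochondrial serine enzyme SHMT2 (-0.46, SE 0.0652, camera adjusted p = 6.02e-10, adjusted p = 0.543 with an estimated correlation). Of 32 lysosome and autophagy genes 4 rose, the autophagy receptor SQSTM1 (0.68, SE 0.124), the peptidase TPP1 (0.52, SE 0.0958), RRAGD (0.62, SE 0.116) and the cathepsin CTSF (0.70, SE 0.15). Adjusted over the list alone 17 rose and 1 fell (camera adjusted p = 2.1e-08, adjusted p = 0.543 with an estimated correlation). YAP and SRF targets had 5 of 16 higher, including CRIM1 (0.43, SE 0.0525), tropomyosin TPM1 (0.51, SE 0.0642) and ANKRD1 (0.80, SE 0.138), and 6 when adjusted over the list alone (camera adjusted p = 0.000611, adjusted p = 0.543 with an estimated correlation). Hypoxia genes had 1 higher, MXI1 (0.80, SE 0.0955), and 5 lower, including the prolyl hydroxylases EGLN3 (-1.63, SE 0.268) and P4HA1 (-0.67, SE 0.118) and the mitophagy receptor BNIP3 (-0.65, SE 0.0729), with 1 and 7 when adjusted over the list alone (camera adjusted p = 0.00347, adjusted p = 0.677 with an estimated correlation). All 30 proliferation genes had negative values and 2 fell, MCM3 (-0.40, SE 0.0814) and AURKA (-0.39, SE 0.0856), or 13 when adjusted over the list alone (camera adjusted p = 5.64e-11, adjusted p = 0.543 with an estimated correlation). All 13 replication histones were negative, with HIST1H2BD lower (-0.42, SE 0.0961) and 9 lower when adjusted over the list alone (camera adjusted p = 3.57e-07, adjusted p = 0.543 with an estimated correlation). Of 78 ribosomal protein genes 69 had positive values, with RPL13A (0.51, SE 0.0673) and RPL37 (0.27, SE 0.0555) called by both adjustments (camera adjusted p = 1.31e-06, adjusted p = 0.543 with an estimated correlation). All 17 other TOP genes were positive, with EIF4B (0.31, SE 0.0579) and EEF2 (0.26, SE 0.0511) called and 4 when adjusted over the list alone (camera adjusted p = 3.28e-06, adjusted p = 0.39 with an estimated correlation, fry adjusted p = 0.0111).

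Whether rapamycin acted differently in the lines was tested as an interaction. By edgeR 0 genes passed, with 156 at an unadjusted p under 0.05 and 0 by DESeq2, and without both shNC libraries rich in olfactory receptor reads 3 passed. BCDIN3D and ALDOC had interactions of 0.83 (SE 0.461) and 0.08 (SE 0.76), each with an edgeR adjusted p of 1. Some gene lists passed by camera in the interaction. The rapamycin change of proliferation genes had a median of -0.166 in shNC and -0.346 in shBCDIN3D (interaction median -0.212, camera adjusted p = 8.78e-11, and adjusted p = 0.799 with an estimated correlation).

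The mature microRNAs were compared because BCDIN3D acts on microRNA precursors, with the let-7 family named by the study. The 9 let-7 guides, which repress growth-promoting messenger RNAs, took 19.1% and 8.03% of microRNA counts in untreated shNC replicates 1 and 2 and 11.6% and 7.5% in untreated shBCDIN3D replicates 1 and 2. The means were 13.6% ± 7.82 and 9.56% ± 2.92 (SD, n = 2). With rapamycin the shares were 7.44% and 7.15% in shNC and 12% and 14.3% in shBCDIN3D, or 7.3% ± 0.203 and 13.1% ± 1.6. The widest 95% Wilson interval was 7.09% to 7.8%, in shNC rapamycin replicate 1. The smallest exact permutation p for 2 against 2 libraries is 0.333, and no test of these shares was made. In the edgeR fit let-7a changed by a log2 of -1.80 untreated (SE 1.41, 95% interval -4.56 to 0.953), let-7d by -2.17 (SE 1.39) and let-7i by -2.15 (SE 1.4), and the 9 values ranged from -2.17 to -0.35 with every interval including 0. The median of the family was -1.80 untreated (camera adjusted p = 4.08e-06, adjusted p = 0.164 with an estimated correlation, fry adjusted p = 0.389) and 1.04 with rapamycin (camera adjusted p = 0.0842). The rapamycin change in shNC had a median of -2.38 (camera adjusted p = 0.000364, adjusted p = 0.377 with an estimated correlation). Without shNC untreated replicate 1 the untreated median was 0.07 (camera adjusted p = 0.921) and the rapamycin median in shNC -0.38 (camera adjusted p = 0.869). That library had a TMM factor of 0.368 and the highest share of small RNA counts on microRNA precursor references (42.2%). The highest share on rRNA (73.4%) was in shBCDIN3D untreated replicate 1.

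**Figure D5:**
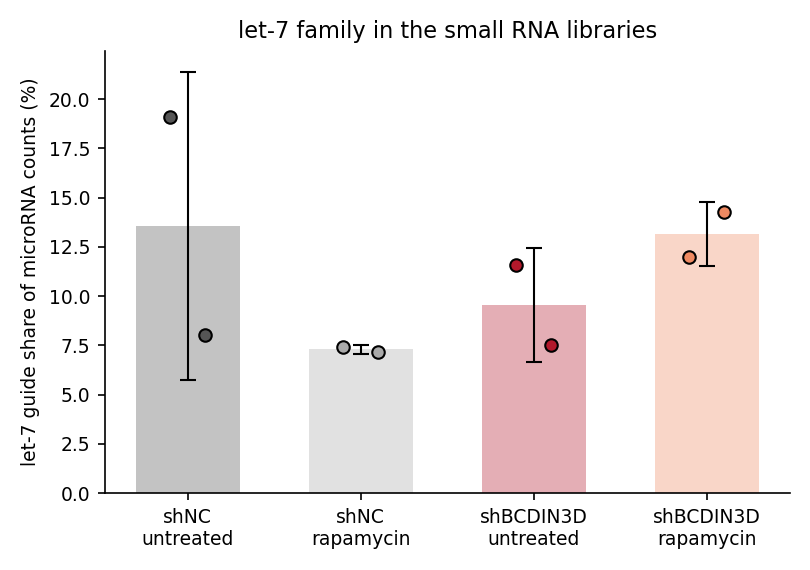
Share of all microRNA counts taken by the 9 let-7 guides (%) in the 4 groups, with bars for the mean, whiskers for the SD and a point for each of the 2 libraries per group. The untreated shNC libraries lie at 19.1% and 8.03%, farther apart than the group means of 13.6% and 9.56%.

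No single microRNA passed in any comparison. By edgeR 0 of 2550 were called in the untreated and rapamycin comparisons of the lines, in the rapamycin comparisons of shNC and shBCDIN3D and in the interaction, with 27, 58, 76, 42 and 29 at an unadjusted p under 0.05, and DESeq2 called 0 in the first 3 listed and in the interaction. As lists in the untreated comparison, the miR-17/92 family (13 microRNAs, median -1.20, camera adjusted p = 1.8e-08), the miR-30 family (5, -1.80, 7.7e-07), abundant mesenchymal microRNAs (12, -1.22, 3.36e-07), the miR-200 family (5, -1.28, 0.00262) and the let-7 passenger strands (11, -0.71, 0.00296) were lower by camera, like the let-7 guides, each with adjusted p = 0.164 with an estimated correlation. Without shNC untreated replicate 1 their medians were -0.33 (camera adjusted p = 0.000637), -0.55 (0.00079), -0.05 (0.00238), -0.68 (0.167) and -0.35 (0.212) in that order, with adjusted p = 0.548 to 0.644 with an estimated correlation, so the last 2 no longer passed. The list of miR-451a with 3 mirtrons, which bypass parts of the usual maturation (4, median -1.09, camera adjusted p = 0.0621), did not pass. Nor did the list of miR-145 and miR-23b with their cluster neighbours miR-143, miR-27b and miR-24 (8, median 0.27, camera adjusted p = 0.699). The median over all microRNAs was 0.269. Among 13466 small RNA features 0 passed untreated by edgeR, with 108 at an unadjusted p under 0.05 and 1 by DESeq2. The microRNA libraries held 706774 to 1417097 counts untreated and 21167 to 361159 with rapamycin. The small RNA libraries held 3701518 to 15294219 untreated and 89272 to 2543749 with rapamycin. Every rapamycin library was thus smaller than every untreated one. Depth was not separated from rapamycin in the small RNA comparisons, let-7 included. On simulated counts, 4-fold changes were not detectable at this depth and spread.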

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

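Leaving out single libraries and the raw let-7 shares were set beforehand for the untreated let-7 change, while their use as tests of explanations, and the tests of the interaction without a library, were chosen after the results had been seen. Each result below was picked out because a list passed by camera in the interaction, that is, its rapamycin change differed between shBCDIN3D and shNC at the preset correlation. None passed with an estimated correlation, where adjusted p was 0.799 to 0.882 for gene lists and 0.338 for microRNA lists, or by fry, where it was 0.811 to 0.979 and 0.659.

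Proliferation genes had a rapamycin change with a median of -0.166 in shNC and -0.346 in shBCDIN3D, and 30 of 30 interaction values were negative (median -0.212, camera adjusted p = 8.78e-11, adjusted p = 0.799 with an estimated correlation). Replication histones had -0.16 and -0.438, with 13 of 13 interaction values negative (median -0.293, camera adjusted p = 1.12e-08, adjusted p = 0.799 with an estimated correlation). Ribosomal protein genes had 0.15 and 0.0614, with 68 of 78 negative (median -0.103, camera adjusted p = 3.38e-06, adjusted p = 0.799 with an estimated correlation). Amino acid synthesis and ATF4 genes had -0.278 and -0.396, with 18 of 26 negative (median -0.0858, camera adjusted p = 0.00611, adjusted p = 0.882 with an estimated correlation). YAP and SRF targets had 0.318 and 0.241, with 14 of 16 negative (median -0.122, camera adjusted p = 0.0366, adjusted p = 0.882 with an estimated correlation). Partners of histidine tRNA had 0.0745 and -0.0993, with 5 of 5 negative (median -0.177, camera adjusted p = 0.0378, adjusted p = 0.799 with an estimated correlation). Outside the runs of neighbouring genes, 4 of these partners were left and the list no longer passed (camera adjusted p = 0.0727), while the other gene lists above did.

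The miR-17/92 family had an interaction median of 1.45 (camera adjusted p = 0.000337, adjusted p = 0.338 with an estimated correlation), and 0.867 without shNC untreated replicate 1, where it no longer passed (camera adjusted p = 0.087). Abundant mesenchymal microRNAs had 1.86 (camera adjusted p = 0.000187, adjusted p = 0.338 with an estimated correlation), and 0.331 without that library (camera adjusted p = 0.0498, adjusted p = 0.743 with an estimated correlation). The miR-30 family had 1.75 (camera adjusted p = 0.0029, adjusted p = 0.338 with an estimated correlation), and 0.872 without that library, where it no longer passed (camera adjusted p = 0.178).

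The let-7 guides had an interaction median of 2.91 (camera adjusted p = 4.89e-06, adjusted p = 0.338 with an estimated correlation), from -2.38 in shNC to 0.576 in shBCDIN3D. A single library could account for it, since without shNC untreated replicate 1 the untreated let-7 median went from -1.80 to 0.0729, although the let-7 interaction was still 1.08 (camera adjusted p = 0.0498, adjusted p = 0.743 with an estimated correlation). Scaling could also contribute, since the raw let-7 shares had a log2 ratio of -0.504 untreated, smaller in size than the scaled median. With 2 libraries a group, neither test separates a biological difference in let-7 from these, so the data cannot tell. More small RNA libraries of similar depth would be needed.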

How the results depend on the processing

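Of 333 results of named genes in total RNA, each counted once per comparison, 0 reversed under the alternatives as read here, but many lost their call. With libraries left out in turn, direction was read only in the fit with the highest adjusted p. A result with no adjusted p in DESeq2 was counted as unchanged. With some library left out, 42 of 75 calls ended between the lines untreated, 49 of 84 with rapamycin, all 9 and 8 for rapamycin in shNC and shBCDIN3D, 33 of 50 for rapamycin averaged and 15 for the lines averaged, where 86 were kept. Among the 333 results, 2 were weaker with DESeq2 size factors and 6 in DESeq2, 7 were weaker and 2 stronger with no low-count filter, and 1 of 249 was weaker with at least 50 counts in every library. With only the libraries compared 34 of 180 were weaker, without both shNC libraries rich in olfactory receptor reads 141 of 332, and with some library left out 156 of 333. These last steps used fewer libraries, but the cause was not tested for them or for the other changes. A group left with 1 library was assumed to vary like the others. The counts of called genes moved far more than directions did. Untreated, the lines differed in 1531 genes, but in 3026 with no filter (where the median of all genes was -0.364), 949 with only the libraries compared, 696 without both shNC libraries rich in olfactory receptor reads, 980 without genes of the shifted runs (fewer genes) and 594 to 1247 with 1 library left out. With rapamycin the count of 1909 was 580 without those shNC libraries and 653 to 1896 with 1 left out. The averaged count of 4199 was 2076 and 2578 to 4018 in the same steps. Rapamycin in shNC (9) gave 198 in DESeq2, 393 with no filter (median of all genes -0.107), 32 with at least 50 counts, 0 with only the libraries compared, 31 without the shNC libraries rich in olfactory receptor reads and 0 to 12 with 1 left out. In shBCDIN3D (8) the same steps gave 283, 620, 23, 0, 0 and 0 to 6. Averaged (686) it gave 1091 in DESeq2, 1597 with no filter, 66 without those libraries and 74 to 399 with 1 left out. The interaction (0) gave 8 with no filter (median of all genes 0.142) and 3 without those libraries. Small RNA features (0) gave 1 in DESeq2.

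BCDIN3D untreated was -1.37 in DESeq2, -1.36 without both shNC libraries and -1.49 to -1.24 with 1 left out. The call ended in DESeq2, without both shNC libraries and without any of 6 single libraries, and was kept without either shBCDIN3D rapamycin library. ALDOC untreated was -2.18 to -0.682 with 1 left out. The let-7 median of -1.80 reversed to 0.0729 without shNC untreated replicate 1, ranged from -2.58 to 0.0729 over libraries, and was -0.504 from raw shares. It stayed at -2.13 (camera adjusted p = 0.00112) without shBCDIN3D untreated replicate 1, which had the most rRNA, and shNC rapamycin replicate 1, which had the fewest counts. It was -1.69 with DESeq2 size factors, which put the median of all microRNAs at 0.348 against 0.269. Of 120 list tests 46 passed by camera, 0 with an estimated correlation and 3 by fry. A replicate block gave 2674 and 3335 for the lines untreated and with rapamycin, 301, 602 and 2147 for rapamycin in shNC, in shBCDIN3D and averaged, and -1.31 for ALDOC untreated, which passed in that fit (edgeR adjusted p = 0.00344) and not without the block. Differences between replicates 2 and 1 correlated between groups at -0.0739 to 0.323 in total RNA, -0.0106 to 0.25 for microRNAs and 0.111 to 0.237 for small RNA features. The labels tie no replicate number to a shared batch or day, so the numbers were not used as pairs. The alternatives set for ribosome profiling and translational efficiency were not run. The smallest microRNA library held 21167 counts and the microRNA coefficient of variation was 0.678, and how far depth or spread limits these results was not separated.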

Other observations

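The tests in this part were chosen after the results had been seen, except the regroupings of libraries, which were planned. Averaged over the treatments, 4199 of 17459 genes differed between the lines by edgeR with Benjamini-Hochberg, 1977 higher and 2222 lower in shBCDIN3D. Leaving out shNC rapamycin replicate 2, shBCDIN3D rapamycin replicate 1 or shBCDIN3D rapamycin replicate 2 gave 2578, 2795 and 2685, and leaving out both shNC libraries rich in olfactory receptor reads gave 2076. Of 78 ribosomal protein genes 46 fell and 1 rose (55 and 2 when adjusted over the list alone), among them RPL11 (log2 -0.82, SE 0.0669), RPL8 (-0.77, SE 0.0711) and RPL28 (-0.42, SE 0.0593), with a list median of -0.267 (camera adjusted p = 5.56e-13, adjusted p = 0.794 with an estimated correlation, fry adjusted p = 0.0142). Of 17 other TOP genes 9 fell and 2 rose (10 and 2 when adjusted over the list alone), including EEF2 (-0.32, SE 0.0511) and EEF1B2 (-0.40, SE 0.0667, camera adjusted p = 0.0283, adjusted p = 0.794 with an estimated correlation, fry adjusted p = 0.0142). Of 17 inflammatory genes 8 fell (10 when adjusted over the list alone), including IL1B (-3.80, SE 0.682), CXCL1 (-1.81, SE 0.33) and the adhesion receptor ICAM1 (-1.75, SE 0.355, camera adjusted p = 0.000354, adjusted p = 0.794 with an estimated correlation). The sterol synthesis enzyme FDFT1 (-0.56, SE 0.14) and the sterol regulator TMEM97 (-0.62, SE 0.0994) fell, 4 in all of 26 (3 when adjusted over the list alone, camera adjusted p = 0.000798, adjusted p = 0.794 with an estimated correlation). Ribosome biogenesis genes had 9 lower, among them NCL (-0.43, SE 0.0707), and 1 higher (14 and 1 when adjusted over the list alone, camera adjusted p = 0.000981, adjusted p = 0.794 with an estimated correlation). Of the called genes picked by the naming rule for this contrast, 86 kept their call whichever library was left out and 15 did not. Calls ended for 6, 7, 9 and 11 without the shNC libraries (untreated 1 and 2, rapamycin 1 and 2) and 11, 3, 10 and 8 without those of shBCDIN3D in that order.

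The small RNA reads differed in class between libraries. Reads on microRNA precursor references took 42.2% and 17.5% of counts in shNC untreated replicates 1 and 2. They took 7.94% and 18.3% in shBCDIN3D untreated replicates 1 and 2. All small RNA reads came from RNA under 35 nt, so they measure neither whole precursors nor whole tRNAs. Reads on rRNA took 29.2% to 50.1% in 7 libraries and 73.4% in shBCDIN3D untreated replicate 1. Because BCDIN3D modifies histidine tRNA, the share of tRNA reads that fell on that tRNA was compared. It was 1.18%, 1.61%, 1.3% and 1.16% in the untreated shNC and shBCDIN3D libraries and 0.594%, 0.67%, 0.254% and 0.508% with rapamycin. The 91 to 32551 reads on histidine tRNA gave an adjusted p of 0.629 for rapamycin (exact permutation of 4 against 4 libraries, unadjusted p = 0.0286, the smallest possible) and 0.943 for the hairpin (unadjusted p = 0.543), over 22 amino acid classes. The hairpin test took no account of treatment. With rapamycin both shBCDIN3D libraries lay below both shNC libraries, while untreated the lines overlapped. Every rapamycin library lay below every untreated library in this share. However, 1 class alone could not pass after adjustment over 22 classes with this number of libraries. Small RNA counts were separated in the same way, at 3701518 to 15294219 untreated and 89272 to 2543749 with rapamycin. Depth and rapamycin thus cannot be told apart here. The data cannot tell whether rapamycin lowered these reads. Of the 22 classes, alanine tRNA also reached the smallest possible unadjusted p, in the hairpin test (0.0286 by the same permutation, adjusted p = 0.629). Its mean shares were 7.98% in shNC and 5.97% in shBCDIN3D.

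A hypothesis for the neighbouring genes that differ between the lines is that copy number of whole chromosome regions differs, as could arise when stable lines are selected. Of the genes in windows past the threshold in the rapamycin libraries, 90.7% moved the same way in the untreated libraries, which are separate, against 59.9% for all windows, and the steps reach 2-fold at the end of chromosome 10. Any lasting difference between the lines would repeat in this way, so the 90.7% does not tell copy number from other causes. A copy number difference could give such runs, but DNA was not measured. The runs do not hold most of the change, since 73.7% of the genes called untreated lie outside them, 74 genes with no position included. Of the 1457 called genes with a position, 72.4% lie outside. Steps that span few genes or are small would not form a run, so copy number differences elsewhere were not excluded.

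Background reads in shNC untreated replicate 1 and shNC rapamycin replicate 2 could have raised genes in shNC. Without these libraries, 828 of the 830 genes called lower in untreated shBCDIN3D were still tested, and 100% of them were lower averaged over the treatments, against 48.9% of all genes. Their median log2 change was -1.04, against -1.03 with all libraries, so the falls as a set were kept without these libraries. However, shNC untreated replicate 2 and both untreated shBCDIN3D libraries had helped to pick these genes and stayed in. The outcome was thus favoured in advance, and the test cannot exclude this background. The median level of these genes in untreated shNC was 20.2 CPM. Regrouping the 8 libraries in all 34 usable ways, in a model with the other factor, gave as many called genes as the hairpin grouping in 1 way, the real one, with 4986 called against at most 1 otherwise. The same held for rapamycin in 1 of 34 ways, with 1196 against at most 77. In every other grouping the real difference counts as spread between libraries, which lowers the number called. These counts therefore do not measure how many calls would arise by chance.

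Whether the differences between the lines follow from loss of BCDIN3D cannot be told. The untreated and rapamycin changes correlated at r = 0.825, which any stable difference between the lines would also give, since each arm is 1 line with 1 hairpin. A second hairpin, or restoring BCDIN3D, would be the test. BCDIN3D itself fell to 38.7% untreated on 16 to 47 counts per library.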
